A study of Mus musculus with 6 samples.

How the data were processed

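CD4 T cells had been sorted from mesenteric lymph nodes, which drain the gut, as CD3+ B220- TCRb+ CD4+ cells. The donors were 3 specific-pathogen-free (SPF) mice and 3 mice infected for 1 week with Nippostrongylus brasiliensis, a rodent hookworm. Per the labels, each mouse carried its own oligonucleotide-tagged hashtag antibody, and the 3 mice of a condition were pooled into 1 droplet library. Each condition therefore has 1 gene expression, 1 hashtag and 1 T cell receptor (TCR) library, made with a 10x Genomics kit that reads the 5-prime ends of transcripts. Infection and droplet library cannot be told apart in this design. The mouse is the replicate, so p-values measure the spread between mice that shared a library.

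The deposited gene expression matrices hold whole-number UMI counts per gene and barcode, and the hashtag counts stand in the same matrices. The submitters' processing notes name Cell Ranger 7.1.0 and the GRCm39 mouse genome, and the filters applied before deposit are not given in the sources used here. The deposited receptor tables list productive contigs with V and J genes, complementarity-determining region 3 (CDR3) sequences and UMI counts, per the file headers. The matrix and the receptor table used for SPF mice carry a wild-type label in their names; the receptor table belongs to an SPF sample in the series records. Every contig barcode lay in the matrix of its own condition (100% in both), against 3.99% and 4.20% in the other matrix. Genes were taken by the symbols and Ensembl identifiers in the files, and the counts of symbols that occur more than once were kept apart by identifier. No genome coordinates are given, because the reference at hand was of another build than the files. Receptor, histocompatibility, ribosomal and heat shock genes have close copies, so UMIs of pairs such as Hspa1a and Hspa1b may be shared between them.

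Mice were told apart with HTODemux of Seurat 5.3.0 in R 4.3.3 (positive quantile 0.99). Barcodes with 1 hashtag, at least 500 genes, at least 1000 UMIs and at most 8% mitochondrial UMIs were kept. Barcodes with several hashtags were left out as doublets between mice. Scrublet marked 1 SPF and 0 infected barcodes, so it did not work here, and doublets within a mouse were addressed only by leaving out cells with a second TRB chain. That alternative was chosen after the data were seen.

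Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The steps used 2000 variable genes, 30 principal components, 20 neighbours and resolution 1.0, without integration of the 2 libraries. Receptor, immunoglobulin, mitochondrial, ribosomal, X-inactivation and Y-linked genes were left out of the variable genes. Clusters were named from markers fixed before the data were examined, and a cluster without a sufficient marker score kept its number. The score thresholds (2, and 0.4 for naive-like) were set after the data were seen, so the shares of the unnamed clusters are given too. Figures were drawn with matplotlib 3.10.9.

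UMI counts were summed per mouse over all kept cells and within each class with at least 20 cells in every mouse. Sums were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM, filterByExpr) with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of infected over SPF mice. Their SE was derived from the fold change and the F statistic of its test. Levels are CPM, the counts of a gene scaled to the TMM-adjusted sum of UMIs of its mouse and class. The difference between the infection effects in Treg-like and naive-like cells was an interaction with the mouse as a block. Numbers of cells per class were tested with edgeR with the number of kept cells as offset, and an exact two-sided permutation test of the share was run beside it. With 3 mice against 3, that exact test cannot give a p below 0.1. Shares of cells with a UMI of 10 chosen genes were compared after thinning each cell to 2000 UMIs.

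A clone was a set of cells of 1 mouse with the same V genes and CDR3 nucleotide sequences of 1 TRA and 1 TRB chain. Clonal expansion was the share of cells in clones of at least 2 cells, as the mean of 100 equal draws per mouse. V genes were tested with edgeR on numbers of clones. A total of 30 gene lists had been fixed before the data were examined. They cover helper T cell programs, naive and activated states, cytokine and interferon responses, receptor and stress signals, cell cycle, metabolism, trafficking and markers of other cell types. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and with an estimated correlation and fry beside it.

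The genes named were fixed by rule. In all CD4 T cells they are the 10 largest rises and falls among genes past the threshold with at least 10 CPM and no overlap between conditions. Chance alone separates 10% of genes in this way with 3 against 3. Within a class they are the 6 largest each way with at least 20 CPM. Receptor and immunoglobulin segments, X-inactivation and Y-linked genes and names without a symbol were left out of these ranks. Up to 4 members of each list with the smallest p, and members of the Th2, Tfh and Treg lists, could be named too. Genes named outside the rule were chosen after their values were seen, and this is said where they stand. Some genes that the rule names are not reported here.

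Alternatives covered hashtag calls, cell filters, each mouse left out in turn, the hashtag number as a block, DESeq2 1.42.0, size factors, low-count filters, equal numbers of cells, equal class composition, cluster resolution, thinning and clone definitions. After the data were seen, runs were added without cells with a second TRB chain, without cells of other types, without blasts, with the interferon-response cluster counted as naive-like, without cells with a heat shock UMI, with as many cells drawn at random, and with the draw of cells for clones kept when a mouse was left out. The gene, list, class and V gene tests were checked on simulated counts in which 200 genes, or some lists, classes or V genes, had been changed by known amounts. Genes were simulated independently of each other, so the list check leaves out the correlation between members. In Tfh-like cells it called 1 of 18 lists without a changed member. The simulated interaction had a set dispersion of 0.01 and no effect shared by the 2 classes of a mouse. At a simulated 2-fold change, edgeR recovered 90.8% of genes in all CD4 T cells, 95.4% in naive-like, 91.9% in Treg-like, 70.3% in Tfh-like and 95.4% in activated or memory cells, and 67.2% in the interaction. At 1.5-fold these were 76.1%, 69.7%, 65.2%, 23.8%, 53.0% and 20.9%.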

Results

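Single-cell transcriptomes, hashtags and T cell receptors were collected from CD4 T cells of the mesenteric lymph nodes of 3 SPF mice and 3 mice infected for 1 week with the intestinal worm Nippostrongylus brasiliensis. The SPF library held 18086 barcodes and the infected library 14689. Hashtags assigned 15764 SPF barcodes (87.2%) and 12674 infected barcodes (86.3%) that passed the filters to 1 mouse. The SPF mice contributed 6118, 4767 and 4879 cells and the infected mice 4304, 4150 and 4220. Barcodes with more than 1 hashtag made up 10.4% and 7.11% of the libraries, and barcodes with none 2.15% and 6.16%. Kept cells had a median of 5586 UMIs and 2150 genes in SPF mice, and of 7012 UMIs and 2414 genes in infected mice. Their summed UMIs lay between 29802628 and 42991595 per mouse. A median of 1.28% and 1.45% of UMIs was mitochondrial.

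Clustering gave 15 clusters. Naive-like cells formed 3 of them, and 1 of these (cluster 1) held 5743 infected and 142 SPF cells, while cluster 0 held 848 infected and 5756 SPF cells. The genes H2-DMa, Hspa1a, Fam240a, Hspa1b, H2-DMb2 and Bcl2 led cluster 1. The other named clusters were interferon-response, Treg-like (2 clusters), Th1-like, T follicular helper (Tfh)-like, cycling, CD8 T-like and a small B-like and myeloid-like cluster. The Th1-like cluster, led by Ccl5 and Cxcr3, is the whole of the activated or memory conventional class. Clusters 4, 6, 11 and 13 stayed unnamed. Cluster 4 was led by Myb, Eomes, Xcl1 and Sox4, cluster 6 by Egr3, Egr2 and Nr4a1, and cluster 11 by Gzmb, Cxcr6, Gzma and Lgals7. Cluster 13 had a median of 2498 UMIs.

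Class shares were compared to see which CD4 T cell populations differed in size after infection. Tfh-like cells, which help B cells in germinal centres, made up 1.18% ± 0.239 of cells in SPF mice and 4.15% ± 1.20 in infected mice (SD, n = 3 each). Cycling cells were at 0.562% ± 0.0767 and 3.11% ± 1.24. Cluster 11 was at 0.0959% ± 0.0622 and 2.85% ± 0.788, and its cells had a median of 25657 UMIs. The activated or memory class was at 2.69% ± 0.415 and 4.25% ± 0.996. Naive-like cells (52.3% ± 2.48 and 57.4% ± 4.52) and Treg-like cells (11.1% ± 0.350 and 12.2% ± 1.34) differed by less than the test could call.

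In edgeR, the shares of 9 of 12 classes passed the threshold. The log2 ratio was 1.80 for Tfh-like cells (adjusted p = 0.000466), 2.47 for cycling cells (0.000323), 4.86 for cluster 11 (1.54e-05) and 0.66 for the activated class (0.0308). It was 0.13 for naive-like cells (adjusted p = 0.414) and 0.14 for Treg-like cells (0.414). Cluster 4 was at 9.43% ± 1.39 and 5.44% ± 1.40 (adjusted p = 0.0175), cluster 6 at 6.69% ± 0.679 and 5.04% ± 0.142 (0.0422) and cluster 13 at 0.347% and 0.567% (0.0732). CD8 T-like cells, outside the sort gate, were at 0.324% and 0.640% (adjusted p = 0.0247), and B-like and myeloid-like cells at 0.123% and 0.229% (0.0421). The interferon-response cluster held 15.1% ± 4.69 and 4.06% ± 1.31, but its defining genes themselves differed between conditions, so this is not read as a change in cell number. The same holds for clusters 4, 6 and 11, as Eomes (4.60) and Nr4a1 (-0.89) also changed within naive-like cells and Gzmb (3.04) within Treg-like cells. The share of Tfh-like cells carries this limit too, as 7 of 15 tested genes of the Tfh list fell and 2 rose within that class. Clusters 1 and 11 came mostly from the infected library and cannot be told apart from a property of that library. The exact two-sided permutation p was 0.1, the smallest possible, for every class except naive-like and cluster 13 (0.2) and Treg-like (0.3). Leaving out SPF replicate 3 left 4 classes called, leaving out infected replicate 3 left 5, and the activated class lost its call without any 1 mouse except infected replicate 1. Cluster 6 lost its call without any 1 mouse except SPF replicate 2, with hashtags called by ratio, with the hashtag block and without cells with a second TRB chain (adjusted p = 0.0577 to 0.169 in these runs), and cluster 4 without SPF replicate 3 (0.0686). The call of CD8 T-like cells was lost without SPF replicate 2 or 3, without infected replicate 3 and with TMM over classes (0.0620 to 0.0711), and that of B-like and myeloid-like cells in 9 runs, among them 4 that left out 1 mouse (0.0507 to 0.169). With TMM over classes in place of the cell total, the log2 ratio was -0.0129 for naive-like cells, -0.00634 for Treg-like cells and 0.53 for the activated class (adjusted p = 0.0986). At cluster resolution 0.5 the log2 ratio of Tfh-like cells was 1.13 (adjusted p = 0.00234).

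**Figure D1:**
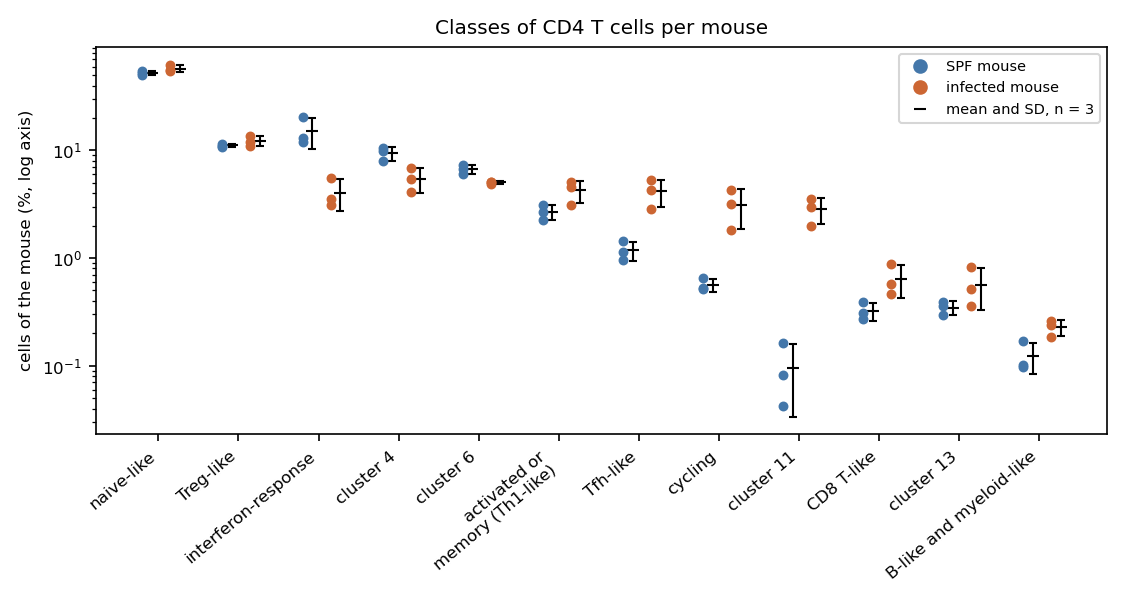
Share of each cell class per mouse, as percent of the kept cells of that mouse on a log axis, with a point per mouse and a line at the mean with its SD for 3 SPF and 3 infected mice. Tfh-like cells lie at a mean of 1.18% in SPF and 4.15% in infected mice, and cluster 11 at 0.0959% and 2.85%.

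Cells with a UMI of single cytokine genes were counted to ask, without clusters, which effector programs were active. After thinning to 2000 UMIs, Il4, the type 2 cytokine that drives class switching to IgE, was seen in 0.242% ± 0.0759 of cells in SPF mice and 2.67% ± 0.887 in infected mice. In naive-like cells, taken as background, the Il4 shares were 0.0485% and 0.0414% at median depths of 5449 and 6688 UMIs. Among Tfh-like cells Il4 was seen in 10.0% of SPF and 28.2% of infected cells, among infected cells of cluster 11 in 24.4% and among infected cycling cells in 15.5%. Mki67, a proliferation marker, was seen in 0.690% ± 0.0879 and 3.15% ± 1.09 of cells, against 0.0485% and 0.138% in naive-like cells. Il13 was seen in 0 of 15665 thinned SPF cells, which allows up to 0.0192% of cells with a UMI at this thinned depth, and in 0.119% of infected cells.

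The exact permutation p was 0.1 for Il4 and Mki67, the smallest possible, and over the 10 genes no adjusted p fell below 0.333. Without thinning, Il4 was at 0.565% and 7.82%, Il13 at 0.00683% and 0.371%, and Mki67 at 1.5% and 7.35%. Summed over cells, Il4 had 164 UMIs in SPF and 6606 in infected mice, a ratio of CPM of 33.6 (95% interval 28.8 to 39.4, counting error only). Il13 had 1 and 761 UMIs (ratio 634, interval 114 to 25085), and Il5 had 2 and 45, of which 41 came from infected replicate 2. Il17a had 319 and 81 UMIs, and 246 of the former came from SPF replicate 1. Il2 had 245 and 649 UMIs (ratio 2.21, interval 1.90 to 2.57, counting error only). Per mouse these were 129, 54 and 62 in SPF and 102, 300 and 247 in infected mice, so the conditions overlapped. Without thinning, at unequal depth, Il2 was seen in 0.747% and 1.48% of cells. Thinned shares of Il21 (0.664% and 0.620%, p = 0.7), Ifng (0.316% and 0.311%, p = 1), Il10 (0.461% and 0.414%, p = 0.8), Il2 (0.254% and 0.310%, p = 0.7), Il17a (0.0966% and 0.0552%, p = 0.6) and Foxp3 (7.01% and 8.22%, p = 0.3) differed by less than exact permutation could separate. Il5 was at 0.0141% and 0.00807%, against 0.0243% in SPF naive-like cells as background, and no direction is read from it. A total of 99 SPF and 64 infected cells were too shallow to be thinned.

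Over all CD4 T cells, Gzmb and Il4 led the rises after infection among genes with at least 10 CPM. Gzmb (ENSMUSG00000015437), which encodes the cytotoxic protease granzyme B, rose by a log2 fold change of 5.52 ± 0.35 (SE), from 2.32 to 108 CPM. Il4 (ENSMUSG00000000869) rose by 5.05 ± 0.36, from 1.62 to 54.9 CPM. The type 2 genes Gata3, the master regulator of Th2 cells (0.94 ± 0.11), Il1rl1, the IL-33 receptor (4.45 ± 0.50), Il17rb, an IL-25 receptor chain (3.65 ± 0.25), Pparg (5.36 ± 0.47) and Ccr4 (1.98 ± 0.13) rose as well. Among the 9 tested members of the Th2 list 7 rose and 0 fell (8 and 0 adjusted over the list alone). The other largest rises were Gzma (4.74), Lgals7 (4.31), S100a6 (3.54), Ifitm2 (3.31), Myo6 (3.10) and the chemokine receptor Cxcr6 (3.00), with the mitotic cyclins Ccnb1 (3.21) and Ccnb2 (2.98).

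All 27 tested cell cycle genes rose, with a median log2 change of 2.15. Of the activated and effector memory list 14 of 15 members rose and 0 fell, among them Lgals1 (1.90 ± 0.14) and Anxa2 (2.88 ± 0.24). Of the Tfh list 11 of 15 rose and 1 fell (12 and 2 adjusted over the list alone), with Tox2 at 1.43 ± 0.10, the checkpoint receptor Pdcd1 at 1.25 ± 0.18 and the follicle-homing receptor Cxcr5 at 1.14 ± 0.17. Il21 was at -0.15 ± 0.20 (adjusted p = 0.596). Of the effector Treg list 8 of 16 rose and 1 fell (9 and 1 adjusted over the list alone), with Ebi3 at 1.63 ± 0.19. The Treg list itself had 5 rises and 1 fall among 17, and Foxp3, its master regulator, was at -0.09 ± 0.06 (adjusted p = 0.265). Genes that led cluster 11 (Gzmb, Gzma, Lgals7, Ifitm2, Myo6, Cxcr6) are among the largest rises over all cells.

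Interferon-stimulated genes were lower in infected mice. Every tested member of the type I interferon response list fell (26 of 26, median -1.07). Ifit3 (ENSMUSG00000074896) fell by 2.22 ± 0.28 on the log2 scale, from 42.3 to 9.04 CPM. Ifit1 (-2.06 ± 0.21), Oasl2 (-1.86 ± 0.25) and Isg15 (-1.24 ± 0.15) fell too, as did the regulator Irf7 (-1.21 ± 0.15). Oasl1 (-1.57), Oas2 (-1.48), Rtp4 (-1.39), Usp18 (-1.25) and Ifi213 (-1.23) complete the 10 largest falls. Of the interferon gamma response list 16 of 20 fell and 0 rose, among them Gbp9 (-0.79 ± 0.07) and Iigp1 (-0.94 ± 0.11).

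Of the naive and central memory list 0 of 13 genes rose and 11 fell (0 and 12 adjusted over the list alone). Ccr7, which guides cells into lymph nodes, fell by 1.06 ± 0.08, and S1pr1, which guides them out, fell by 0.85 ± 0.05. All 9 tested IL-4 response genes rose, with the receptor chain Il4ra at 0.89 ± 0.05. All 12 glycolysis genes rose (Tpi1 1.70 ± 0.13, Gapdh 0.92 ± 0.07), as did 15 of 17 sterol synthesis genes (16 adjusted over the list alone) and 57 of 75 genes of oxidative phosphorylation, of which 1 fell (60 and 1 adjusted over the list alone). Of the mitochondrially encoded genes 6 of 13 rose and 0 fell. Ribosomal protein genes were mixed (24 of 85 rose, 10 fell), and of the trafficking list 2 rose and 6 fell among 14 (3 and 6 adjusted over the list alone), with the gut-homing receptor Ccr9 at 1.88 ± 0.16. The trafficking median was -0.05, its mean 0.05, and the test pointed down.

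Other lists moved both ways. The Th1 list had 4 rises (Nkg7 1.04 ± 0.11) and 3 falls (Fasl -0.88 ± 0.10) among 14, with a median of -0.04 and a mean of 0.39. The Th17 list had 3 rises and 5 falls among 12 (3 and 6 adjusted over the list alone). The TCR-induced list had 3 and 5 among 14 (4 and 6 adjusted over the list alone), with Nr4a1 at -0.99 ± 0.08. The immediate early and stress list had 5 and 8 among 17 (6 and 8 adjusted over the list alone), and its median (0.03) and mean (0.27) lay above 0 while the test pointed down. The IL-2 and STAT5 list had 7 rises and 3 falls among 11.

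Markers of other cell types were looked at beside these groups. Igkc, an antibody light chain, was at 2.96 ± 0.97 (adjusted p = 0.0360) and Cd8a at 1.00 ± 0.30 (0.0256), and without the CD8 T-like, B-like and myeloid-like cells they were at -0.22 and -0.01. The call of Igkc was lost without any 1 SPF mouse, without infected replicate 3 (1.18) and in DESeq2, and that of Cd8a without SPF replicate 2 or 3 and without infected replicate 2 or 3 (0.66 without the latter). Of the B cell list 1 of 10 rose and 1 fell, and of the myeloid list 0 of 6 rose and 1, Ctss (-0.52 ± 0.06), fell. Of the NKT cell list 3 of 6 rose and 1 fell, of the gamma delta T cell list 1 of 2 rose (median and mean 0.28, while the test pointed down), of the CD8 list 1 of 2 rose, and of the stromal list 1 of 2 rose (Col1a1 2.36 ± 0.48, below 1 CPM in every mouse) and 1 fell. None of the 4 NK cell genes and not the 1 erythroid gene passed, and 0 plasma cell genes were expressed enough to be tested.

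In edgeR, 6046 of 15405 genes changed over all CD4 T cells, 3229 up and 2817 down, and DESeq2 called 4922. Camera called 13 of 28 lists, with adjusted p = 0.000112 for Th2, 5.95e-17 for cell cycle, 3.98e-08 for activated and effector memory, 0.000355 for Tfh, 0.00497 for effector Treg, 1.96e-15 for type I interferon, 2.60e-08 for interferon gamma, 5.28e-07 for naive and central memory, 3.30e-06 for IL-4, 1.67e-08 for glycolysis, 1.08e-06 for sterol synthesis, 1.89e-15 for oxidative phosphorylation and 0.00539 for mitochondrially encoded genes. No call holds with an estimated correlation, where the smallest adjusted p is 0.426, and the adjusted p is 0.516 for Tfh, 0.527 for effector Treg and 0.438 for sterol synthesis and oxidative phosphorylation. Other splits of the 6 mice called up to 16 lists, so these statements rest on counts of members and not on the list calls. The counts are descriptions only. Members of a list vary together (estimated correlation 0.93 for cell cycle and 0.77 for type I interferon) and are not independent of each other. Over all genes 3229 of 15405 rose and 2817 fell, and the Th1, Treg and ribosomal counts lie near those shares. These changes include changes in composition: with the same number of cells of each class from every mouse 3279 genes were called, 2601 of them in both, and the Tfh, effector Treg and interferon gamma lists (medians 0.23, 0.11 and -0.08) lost their calls. There Icos, Nkg7, Il1r1, Entpd1, Ebi3 and Iigp1 were no longer called, Il21 was at -0.84 and called, and without cycling cells and cluster 11 the count was 3590.

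**Figure D2:**
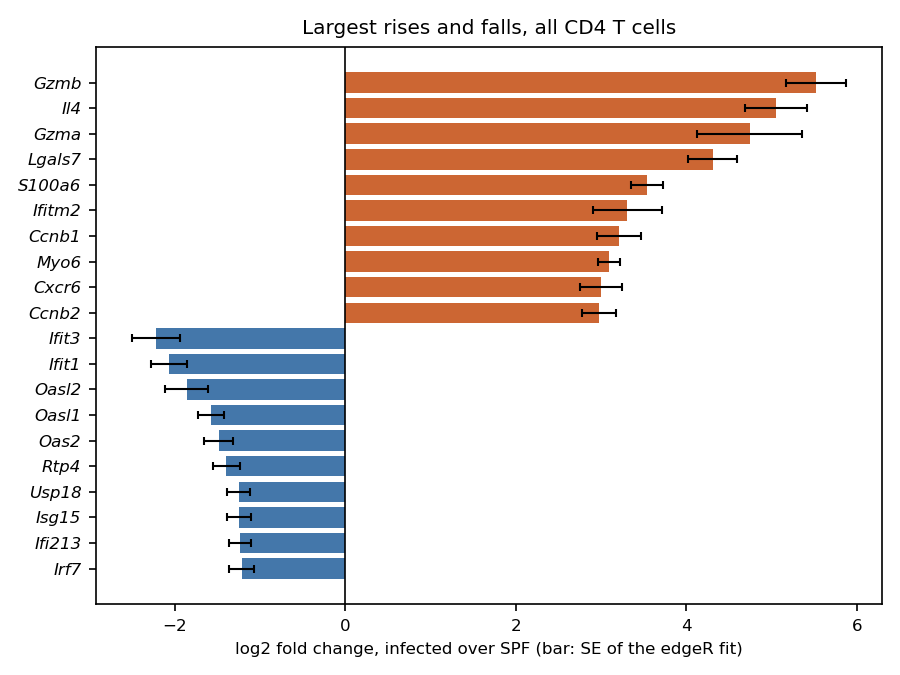
The 10 largest rises and the 10 largest falls over all CD4 T cells, with log2 fold changes of infected over SPF mice (n = 3 each) on the horizontal axis and error bars for the SE derived from the edgeR F statistic. Gzmb stands at 5.52 and Ifit3 at -2.22.

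Naive-like cells were compared alone to ask whether cells that had not become effectors differed after infection. H2-DMa (ENSMUSG00000037649), a subunit of the chaperone that loads peptides on MHC class II, rose by a log2 fold change of 3.54 ± 0.10, from 33.6 to 391 CPM. Il4ra (ENSMUSG00000030748) rose by 1.42 ± 0.07, from 109 to 293 CPM, and the cytokine signalling inhibitors Socs1 and Cish rose by 1.33 ± 0.10 and 1.70 ± 0.14. The survival gene Bcl2 rose by 1.67 ± 0.12, from 181 to 576 CPM. The heat shock genes Hspa1a (3.20 ± 0.52) and Hspa1b (2.85 ± 0.47) rose as well.

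Fam240a (2.73), Cst7 (2.44) and Ppp3cc (2.14) complete the 6 largest rises, and Eomes, a T-box factor, rose by 4.60 ± 0.24 to 11.4 CPM. The largest falls were Dusp5 (-1.34), Zfp36l2 (-0.98), Nr4a3 (-0.98), Neurl3 (-0.90), Nr4a1 (-0.89) and Gramd3 (-0.87). Of the IL-4 response list 4 of 9 members rose and 0 fell, and of the IL-2 and STAT5 list 5 of 10 rose and 2 fell (6 and 2 adjusted over the list alone). The trafficking list had 1 rise and 6 falls among 12 (2 and 6 adjusted over the list alone), with Ccr7 at -0.65 ± 0.04, S1pr1 at -0.63 ± 0.04 and Itgb7 at -0.38 ± 0.04. The activated and effector memory list had 1 rise and 7 falls among 12 (1 and 9 adjusted over the list alone), with Vim at -0.63 ± 0.05, S100a10 at -0.61 ± 0.04 and Lgals3 at 5.04 ± 0.38. Its median was -0.42, its mean 0.01 and the test pointed down. Of the ribosomal protein genes 65 of 84 rose and 0 fell (72 and 1 adjusted over the list alone), and of the glycolysis genes 7 of 10 rose (8, with 1 fall, adjusted over the list alone). Oxidative phosphorylation had 19 rises and 3 falls among 72 (19 and 4 adjusted over the list alone), and mitochondrially encoded genes 8 and 0 among 13 (10 and 0 adjusted over the list alone).

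Of the interferon gamma response list 7 of 20 rose and 1 fell (8 and 1 adjusted over the list alone), with Igtp at 0.37 ± 0.05 and Ifi47 at 0.31 ± 0.05. In cells without a heat shock UMI Igtp (0.20) was not called, nor was it in as many cells drawn at random (0.31). This depends on the class: with the interferon-response cluster counted as naive-like, the list median was -0.27, Igtp was at -0.25 and Ifi47 at -0.02, and the IL-2 and STAT5 list (median 0.22) lost its call. The type I interferon list had 3 rises and 9 falls among 24 (4 and 9 adjusted over the list alone) and was not called (adjusted p = 0.173). The naive and central memory list had 5 rises and 6 falls among 13.

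In edgeR, 3080 of 12756 genes changed in naive-like cells, 1512 up and 1568 down, against 1984 in DESeq2. Camera called 9 of 24 lists, IL-4 (adjusted p = 0.00468, and 0.311 with an estimated correlation), IL-2 and STAT5 (0.0332, and an adjusted p of 0.618 with an estimated correlation), trafficking (0.00279, then 0.311), activated and effector memory (8.83e-05, then 0.202), interferon gamma (0.00500, then 0.279), ribosomal (4.97e-32, then 0.311), glycolysis (0.00154, then 0.311), oxidative phosphorylation (0.00279, then 0.721) and mitochondrially encoded genes (1.89e-06, then 0.202). Fry did not call the IL-2 and STAT5 and the oxidative phosphorylation list. Another split of the mice called 8 lists. Different clusters hold most of the class in the conditions, cluster 1 in infected and clusters 0 and 2 in SPF mice, and H2-DMa and the heat shock genes are among the genes that lead cluster 1. A UMI of Hspa1a or Hspa1b was present in 18.4%, 30.2% and 57.1% of naive-like cells of the SPF mice and in 85.4%, 89.8% and 93.7% of those of the infected mice. In cells without such a UMI 810 genes were called, against 1043 in as many cells drawn at random, with H2-DMa at 3.37, Il4ra at 1.34, Socs1 at 1.22, Cish at 1.67 and Bcl2 at 1.59. Cd74, an abundant transcript of B and myeloid cells, was at 0.28 ± 0.19 (adjusted p = 0.314) in naive-like cells.

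**Figure D3:**
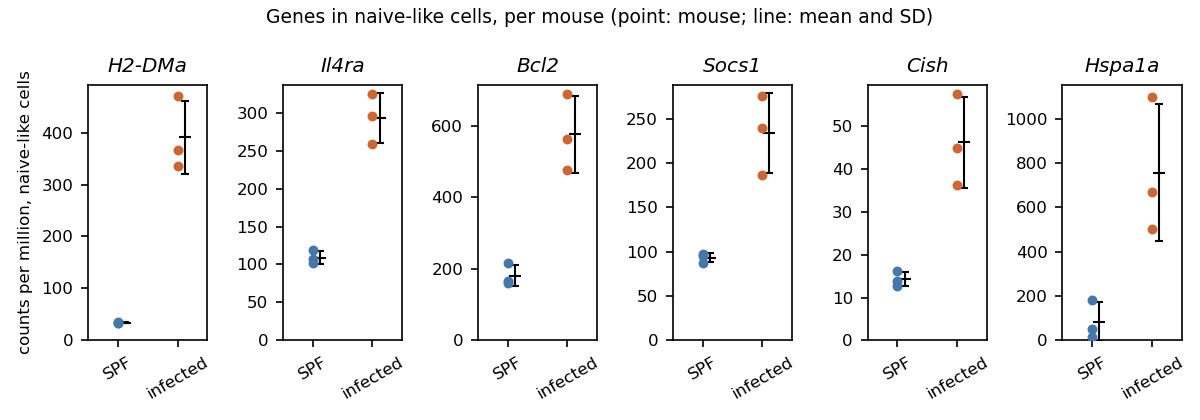
Levels of H2-DMa, Il4ra, Bcl2, Socs1, Cish and Hspa1a in naive-like cells in CPM, with a point per mouse and a line at the mean with its SD for 3 SPF and 3 infected mice. H2-DMa lies at a mean of 33.6 in SPF and 391 in infected mice.

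Treg-like cells were compared to ask how regulatory cells differed after infection. Gzmb rose by a log2 fold change of 3.04 ± 0.28, from 14.6 to 122 CPM, and Il1rl1, the IL-33 receptor of tissue Treg cells, by 2.81 ± 0.45. Il4ra (1.00 ± 0.10), Cish (0.67 ± 0.08), Batf (0.57 ± 0.09), the latent TGF-beta receptor Lrrc32 (0.73 ± 0.07) and Il2ra (0.43 ± 0.05) rose too. Foxp3 was at 0.07 ± 0.06 (adjusted p = 0.575). The effector Treg list had 3 rises and 2 falls among 16 (4 and 2 adjusted over the list alone). Type I interferon response genes were lower, with 16 of 26 falling and 0 rising (0 rises and 22 falls adjusted over the list alone, median -0.61).

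Hspa1a (3.47), Hspa1b (3.18), Pros1 (1.58), S100a4 (1.46) and H2-DMa (1.35) were the other large rises. The largest falls were Ifit1 (-1.55), Ifit3 (-1.44), Nr4a3 (-1.02), Rgs16 (-0.98), Sccpdh (-0.98) and Irf7 (-0.92). The receptors Il23r (-1.98 ± 0.42) and Ccr6 (-0.82 ± 0.18), both members of the Th17 list, fell. Of the IL-4 response list 5 of 9 rose and 0 fell (6 and 0 adjusted over the list alone), of the IL-2 and STAT5 list 7 of 11 rose and 0 fell (7 and 1 adjusted over the list alone), and of the activated and effector memory list 7 of 13 rose and 0 fell (9 and 1 adjusted over the list alone). Glycolysis genes rose in 6 of 11 cases (9 adjusted over the list alone). The Treg list had 2 rises and 1 fall among 17 (3 and 2 adjusted over the list alone) and was not called (adjusted p = 0.243). The Th2 list had 2 rises and 0 falls among 5, naive and central memory 0 and 2 among 13 (0 and 4 adjusted over the list alone), TCR-induced 0 and 2 among 14 (2 and 4), cell cycle 2 and 0 among 20 (2 and 0), sterol synthesis 2 and 0 among 17 (5 and 0), ribosomal proteins 24 and 0 among 81 (33 and 0), oxidative phosphorylation 15 and 0 among 72 (19 and 0), mitochondrially encoded genes 4 and 0 among 11 (6 and 0) and myeloid markers 0 and 1 among 2.

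The fall in the Treg list was Il10 (-0.59 ± 0.15, adjusted p = 0.0218), a call that was lost without SPF replicate 2, SPF replicate 3 or infected replicate 1 (-0.56, -0.56 and -0.43), and the value was 0.08 in cells without a heat shock UMI and -0.38, not called, in as many cells drawn at random. Nor was Il10 called at resolution 0.5 (-1.26) or 1.5 (-0.53). S100a4 and the chemokine receptor Cxcr3 (0.89 ± 0.19) depend on how the class is drawn as well: at resolution 0.5 they were at -0.03 and -0.35. Without infected replicate 1, Cxcr3 was at 0.65 and no longer called. S100a4 was at 0.11 and Sccpdh at -0.82, both uncalled, at resolution 1.5. DESeq2 gave no adjusted p for Il1rl1 and Il23r and did not call Il10, and Ccr6 was at -0.23 and not called both in cells without a heat shock UMI and in as many cells drawn at random.

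In edgeR, 663 of 10568 genes changed in Treg-like cells, 416 up and 247 down, against 349 in DESeq2. Camera called 15 of 24 lists, among them type I interferon (adjusted p = 1.66e-21, and 0.211 with an estimated correlation), IL-4 (4.91e-07, and an adjusted p of 0.0776 with an estimated correlation), IL-2 and STAT5 (8.93e-07, then 0.158), activated and effector memory (2.74e-08, then 0.0884), glycolysis (5.95e-10, then 0.0776) and effector Treg (0.0316, then 0.596). No call of these 15 holds with an estimated correlation. The effector Treg call was lost without SPF replicate 2 (median 0.08) and without infected replicate 2 (0.01), the Th2 call without infected replicate 2 (-0.02), and the TCR-induced and cell cycle calls without SPF replicate 1, infected replicate 1 or infected replicate 3. Fry did not call these 4 lists or the naive and central memory, sterol synthesis and ribosomal lists, nor the type I interferon list (adjusted p = 0.0788), and another split of the mice called 13 lists by camera. A heat shock UMI was present in 6.34%, 12.2% and 28.3% of Treg-like cells of the SPF mice and in 56.8%, 60.3% and 78.5% of those of the infected mice, and in cells without one 391 genes were called, against 327 in as many cells drawn at random. Hspa1a was at 5.25 without SPF replicate 3.

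Tfh-like cells were compared to ask whether their program differed, beside their share of cells. Il4 rose by a log2 fold change of 2.02 ± 0.20, from 64.5 to 281 CPM, while Il21, the classical Tfh cytokine, fell by 1.80 ± 0.14, from 156 to 43.8 CPM. Bcl6, the master regulator of Tfh cells, fell by 0.94 ± 0.11, from 223 to 117 CPM. CPM are relative to all transcripts of the cells, whose median depth was 5249 UMIs in SPF and 13580 UMIs in infected mice. A fall in CPM in this class need not be a fall in transcripts per cell. The Th1 genes Ifng (-3.21 ± 0.42), Tbx21 (-3.16 ± 0.54), Gzmk (-3.05 ± 0.35) and Cxcr3 (-1.16 ± 0.28) fell, and the type 2 genes Ccr4 (1.85 ± 0.25) and Il17rb (3.82 ± 0.62) rose. The Treg genes Foxp3 (-2.94 ± 0.54) and Ikzf2 (-2.10 ± 0.16) fell too, so the SPF cluster carried more of their transcripts.

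The largest rises were Myo6 (4.78), S100a4 (4.06), S100a6 (3.86), Epas1 (3.40), Cd7 (3.23) and Hspa1b (2.70). The largest falls were Cxxc5 (-4.43), Rgs16 (-3.84), Ier5l (-3.83), Ascl2 (-3.52), Itgb8 (-3.48) and Pard6g (-3.16). Of the Tfh list 2 of 15 rose and 7 fell (3 and 8 adjusted over the list alone), among the falls Sostdc1 (-2.04 ± 0.17) and Tox (-0.96 ± 0.09). Pdcd1 was at -0.68 ± 0.11 and Maf at -0.62 ± 0.11, but at resolution 0.5 Pdcd1 was at 0.17 and Bcl6 at -0.20, no longer called. In cells without a heat shock UMI Pdcd1 (-0.31) and Maf (-0.41) were not called, nor were the Tfh (median -0.30), trafficking (-0.13), type I interferon (-0.14), TCR-induced (-0.16) and mitochondrially encoded (0.34) lists. Foxp3 (-1.80) was not called in as many cells drawn at random. Of the Th1 list 0 of 5 rose and 4 fell (0 and 5 adjusted over the list alone), of the Th2 list 4 of 5 rose and 1, Areg (-3.37 ± 0.42), fell, and of the interferon gamma list 0 of 15 rose and 8 fell (0 and 9 adjusted over the list alone). The Treg list had 1 rise and 5 falls among 11 (1 and 8 adjusted over the list alone). Of the 80 ribosomal protein genes 76 rose and 0 fell (78 and 0 adjusted over the list alone), and 8 of 11 glycolysis genes rose. Of the trafficking list 6 of 11 rose and 0 fell (6 and 1 adjusted over the list alone), among them Gpr183 (1.20 ± 0.12). The type I interferon list had 0 rises and 4 falls among 18 (1 and 5 adjusted over the list alone), activated and effector memory 8 and 1 among 12 (8 and 1), IL-2 and STAT5 0 and 4 among 7 (0 and 4), TCR-induced 1 and 4 among 14 (1 and 6), immediate early and stress 2 and 7 among 16 (2 and 8), cell cycle 6 and 1 among 16 (6 and 1), oxidative phosphorylation 39 and 0 among 72 (51 and 3) and mitochondrially encoded genes 5 and 0 among 9 (5 and 1), and both tested Th17 genes rose.

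In edgeR, 1574 of 8574 genes changed in Tfh-like cells, 865 up and 709 down. Camera called 17 of 24 lists, among them Tfh (adjusted p = 0.00127, and 0.169 with an estimated correlation), Th1 (0.000103, and an adjusted p of 0.150 with an estimated correlation), Treg (0.000493, then 0.230), interferon gamma (0.000477, then 0.230), ribosomal (6.92e-66, then 0.150), glycolysis (4.73e-07, then 0.169), trafficking (0.00757, then 0.150) and type I interferon (0.0496, then 0.529). No call of these 17 holds with an estimated correlation. The Th2 call (adjusted p = 0.0205, then 0.233) was lost without SPF replicate 2 (median 1.04, adjusted p = 0.342) and without SPF replicate 3 (1.93, 0.0513). The type I interferon call was lost without SPF replicate 2 or 3 and without infected replicate 2 or 3 (medians -0.23 to -0.0948), the TCR-induced call without SPF replicate 3 (-0.28) or infected replicate 1 (-0.48), and the cell cycle call without any 1 infected mouse (0.16 to 0.31), and fry did not call the first 2 of these. Another split of the mice called 10 lists. The class is small and unequal in depth, with 302811 to 545171 summed UMIs per SPF mouse and 1668890 to 3145620 per infected mouse, and median UMIs per cell of 5249 and 13580. With equal numbers of cells from each mouse 799 genes were called, and 979 in cells without a heat shock UMI, against 923 in as many cells drawn at random. A heat shock UMI was present in 9.09%, 15.2% and 35.7% of Tfh-like cells of the SPF mice and in 71.8%, 69.3% and 81.1% of those of the infected mice. Without SPF replicate 1, Myo6 was at 9.68 and Il17rb at 8.71, and without infected replicate 3 Foxp3 was at -4.81.

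The activated or memory conventional class was compared to ask what differed in non-follicular, non-regulatory effector cells, and it holds the Th1-like cluster alone, without cycling cells and cluster 11. Of the tested Th1 genes 6 of 12 were lower, and of the Th17 genes 7 of 9. Cxcr3 was at -0.92 ± 0.13, from 218 to 112 CPM, the IL-18 receptor Il18r1 at -0.92 ± 0.14, and Ccr6, a chemokine receptor of Th17 cells, at -1.81 ± 0.19. Gata3 (0.97 ± 0.13), Il4 (1.34 ± 0.28) and Ccr4 (0.80 ± 0.13) rose. Satb1 (1.18 ± 0.13), Klf2 (0.65 ± 0.09) and S1pr1 (0.57 ± 0.09), which are high in naive cells, rose as well.

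Myo6 (4.74), Smtn (3.63), Hspa1b (2.88), Hspa1a (2.75) and Pdlim4 (2.30) were among the largest rises, and Serpina3g (-2.19), Cxcl10 (-2.14), Ctsw (-1.92), Iigp1 (-1.85) and Ramp1 (-1.59) fell most beside Ccr6. Of the Th17 list 0 of 9 rose and 7 fell (0 and 8 adjusted over the list alone), among them Tmem176b (-1.26 ± 0.19) and Tmem176a (-1.19 ± 0.21). Of the Th1 list 0 of 12 rose and 6 fell (1 and 8 adjusted over the list alone), with Gzmk at -1.54 ± 0.32. All 3 tested Th2 genes rose. The naive and central memory list had 9 rises and 1 fall among 13, the activated list 8 rises and 1 fall among 14 (10 and 1 adjusted over the list alone), with S100a6 at 1.83 ± 0.09 and Itgb1 at 1.63 ± 0.12, the type I interferon list 0 rises and 10 falls among 25 (0 and 11 adjusted over the list alone), with Mx1 at -1.54 ± 0.28, and the interferon gamma list 0 and 10 among 19 (0 and 12 adjusted over the list alone). The Treg list had 1 rise and 4 falls among 13 (1 and 7 adjusted over the list alone), among them Ikzf2 (-1.06 ± 0.14) and Ctla4 (-0.77 ± 0.12), and Il21 fell by 2.47 ± 0.37. The trafficking list had 7 rises and 2 falls among 13 (7 and 3 adjusted over the list alone), TCR-induced 0 and 6 among 13 (0 and 8), glycolysis 5 and 0 among 10 (9 and 0), ribosomal proteins 37 and 0 among 80 (47 and 1), oxidative phosphorylation 9 and 0 among 72 (9 and 0), mitochondrially encoded genes 3 and 0 among 9 (5 and 0) and sterol synthesis 1 and 0 among 15 (1 and 0), and 0 of 2 myeloid and 0 of 3 NKT markers passed. Cd74 was at -1.71 ± 0.38, a call that was lost without SPF replicate 1 (-1.27), without infected replicate 2 (-1.48) and in DESeq2.

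In edgeR, 606 of 8464 genes changed in this class, 335 up and 271 down, against 313 in DESeq2, and 385 with equal numbers of cells from each mouse. Camera called 17 of 24 lists, among them Th17 (adjusted p = 6.75e-09, and 0.0947 with an estimated correlation), Th1 (1.82e-06, and an adjusted p of 0.0606 with an estimated correlation), Th2 (1.82e-05, then 0.0598), naive and central memory (9.42e-10, then 0.0598), activated (2.34e-10, then 0.0598), type I interferon (4.08e-08, then 0.261), interferon gamma (2.56e-10, then 0.123) and Treg (0.000139, then 0.123). Another split called 15. The call of Cxcl10 was lost without SPF replicate 1 (-1.41), and the value was -3.38 without infected replicate 2. Without SPF replicate 3, Hspa1b was at 4.40 and Hspa1a at 4.57. DESeq2 did not call Cxcl10, Gzmk, Il4 or Hspa1a, and with equal numbers of cells Cxcl10, Gzmk and Ramp1 were not called. Fry did not call the type I interferon, Treg, sterol synthesis and NKT lists, no call of the 17 holds with an estimated correlation, and single mice ended the calls of sterol synthesis (infected replicate 2, median 0.10), myeloid (SPF replicate 3, infected replicate 1 or 3) and NKT lists (SPF replicate 3, infected replicate 1). A heat shock UMI was present in 13.9%, 26.9% and 54.3% of these cells in the SPF mice and in 76.3%, 86.2% and 92.2% in the infected mice.

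**Figure D4:**
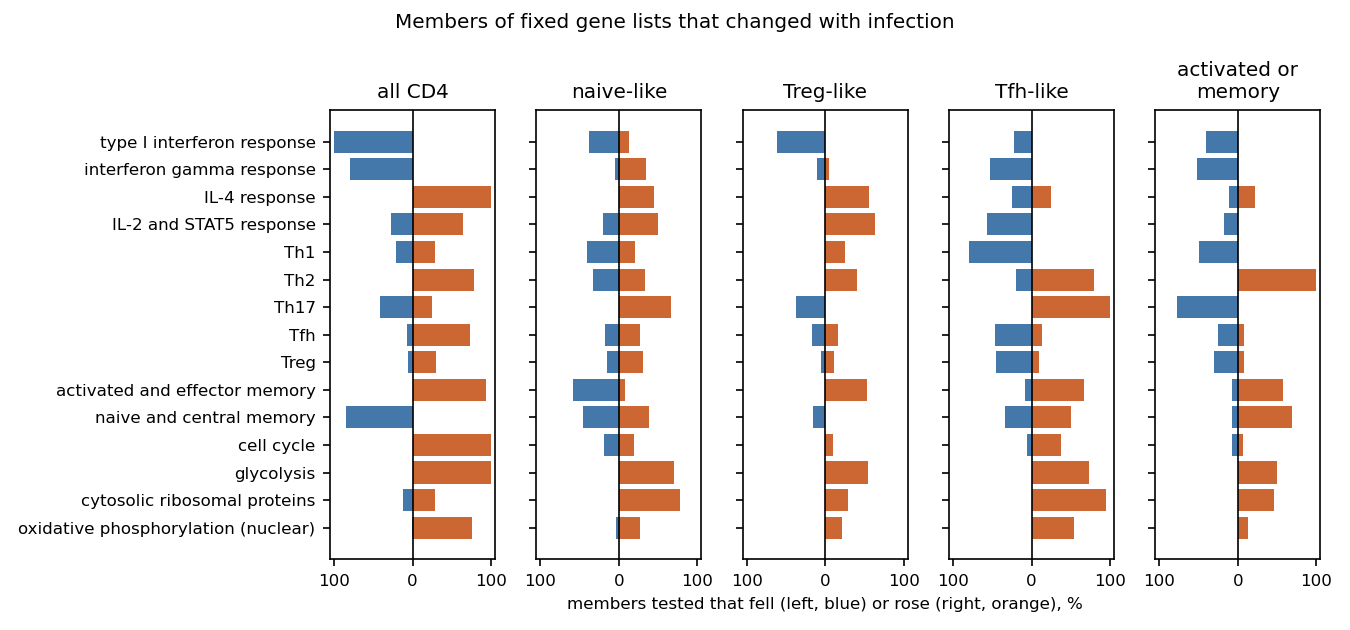
Percent of the tested members of 15 fixed gene lists that fell (left) or rose (right) with infection in all CD4 T cells and in 4 classes, by edgeR at an adjusted p of 0.05 with 3 mice per condition. All 26 type I interferon response genes fell over all CD4 T cells, and 76 of 80 ribosomal protein genes rose in Tfh-like cells.

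The infection effect was compared between Treg-like and naive-like cells of the same mice to find genes that responded in one class more than in the other. H2-DMa rose less in Treg-like cells, by a difference of -2.19 ± 0.08 between the log2 changes, and so did Bcl2 (-1.30), Cish (-1.02), Socs1 (-0.79) and Il4ra (-0.42). Xbp1 was at 0.04 (adjusted p = 0.909). All of these genes rose in naive-like cells, and a choice by that rise favours a smaller change in Treg-like cells. The interferon-stimulated genes Ifit1 (-1.47) and Ifit3 (-1.49) fell more in Treg-like cells than in naive-like cells, which lack the interferon-response cluster by definition. In edgeR with the mouse as a block, the effects of 618 of 12893 genes differed, 353 with a higher and 265 with a lower change in Treg-like cells, and without the block 308 did. Il4ra is among the genes that were not called without the block (adjusted p = 0.151).

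Receptors were compared to ask whether infection was accompanied by clonal expansion. Over all cells, 1.05% ± 0.298 of SPF and 1.72% ± 0.336 of infected cells lay in clones of at least 2 cells in equal draws of 2914 cells. In Treg-like cells the shares were 0.108% ± 0.187 and 1.39% ± 1.07. In Tfh-like cells, with 32 cells drawn, they were 15.2% ± 8.97 and 1.32% ± 0.858, and in activated or memory cells, with 80 drawn, 11.5% ± 5.50 and 2.95% ± 1.38. All 4 comparisons had an exact two-sided permutation p of 0.1, the smallest 3 mice against 3 can give, and the adjusted p over the 4 is 0.1 as well. With hashtags called by ratio the exact permutation p over all cells was 0.2, and without equal draws it was 0.2 over all cells and in Tfh-like cells. The difference in Treg-like cells was 1.28 percentage points, and 0.659 without infected replicate 2. In Tfh-like cells it was -13.8, and -8.92 without SPF replicate 3. Without SPF replicate 2 it was -21.8 with 43 cells drawn and -18.3 with the draw kept at 32. In activated cells the difference of -8.52 became -5.51 without SPF replicate 2 when the draw was kept at 80. There were 58 such clones in SPF and 75 in infected mice, and the largest had 7 and 3 cells. Of the pairs of cells with the same receptor 94.5% and 91.2% carried the same hashtag, against 33.7% and 33.4% of random pairs.

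**Figure D5:**
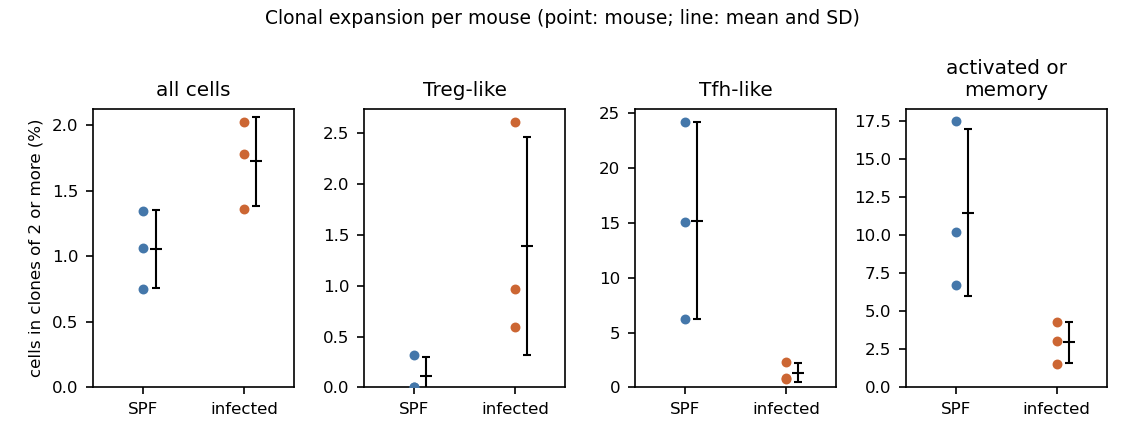
Percent of cells in clones of at least 2 cells per mouse, from equal draws, in all cells and 3 classes, with a point per mouse and a line at the mean with its SD (n = 3 per condition). In Tfh-like cells the means are 15.2% in SPF and 1.32% in infected mice.

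V gene usage was compared over clones to ask whether infection selected receptors with certain V genes. In edgeR, 0 of 69 TRAV genes passed (smallest adjusted p = 0.193, 5 genes at an unadjusted p under 0.05) and 0 of 21 TRBV genes (0.232, 4 genes), and no other tool was run. Without infected replicate 3, 1 TRAV gene passed, at an adjusted p of 0.0469.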

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

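The tests of the 3 patterns against explanations, the splits of the mice and the runs without heat shock UMIs, with random cells and without blasts were chosen after the results had been seen; the interaction, the runs without the block or without 1 mouse, the estimated correlation and fry had been planned.

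The infection effect differed between Treg-like and naive-like cells for 618 of 12893 genes by the interaction test, among them 11 of the 20 genes named for size in either class. Choosing genes by the size of their change in 1 of these classes favours a difference between the 2. The 11 genes are therefore not independent support for a difference. For genes that rose, the change in Treg-like cells was smaller by -2.19 for H2-DMa, -2.00 for Cst7, -0.86 for Ppp3cc and -2.00 for Pros1 on the log2 scale. For genes that fell in naive-like cells, it was less negative by 0.55 for Dusp5, 0.28 for Zfp36l2, 0.53 for Neurl3 and 0.38 for Gramd3, and the difference for Zfp36l2 was not called without SPF replicate 1 (0.22). Without the mouse as a block, Dusp5, Zfp36l2, Neurl3 and Gramd3 were not called (adjusted p = 0.148, 0.290, 0.0580 and 0.404). The interferon-stimulated genes Ifit1 (-1.47), Ifit3 (-1.49) and Irf7 (-0.86) fell more in Treg-like cells. Naive-like cells lack the interferon-response cluster by definition, so this difference may depend on how the class was drawn. The interaction was not run with that cluster counted as naive-like. Barcodes without a hashtag call, which the main comparisons left out, made up 6.16% of the infected library against 2.15% of the SPF library. The runs with hashtags called by ratio did not exclude such barcodes.

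A first pattern is the rise of H2-DMa with the IL-4 response genes Il4ra, Socs1, Cish and Xbp1 in naive-like cells of infected mice, the members that rose of a list of 9 whose median change was 0.13 (adjusted p = 0.311 with an estimated correlation). If heat shock of the cells that hold a heat shock UMI were the cause, the median change of these genes would fall in cells without one. It was 1.34 there against 1.42 in all naive-like cells, although Xbp1 lost its call there (0.31, adjusted p = 0.0706 in edgeR) and in as many cells drawn at random (0.10). The whole list had a median of 0.30 there. The 5 genes were chosen because they rose. Cells without a heat shock UMI went through the same library, so an effect of handling on all its cells would persist in them. This run cannot exclude such an effect. Free RNA of B or myeloid cells would need a rise of Cd74 of 11.47, and Cd74 was at 0.28. A single factor per gene for the whole library would give both classes the same change, but 4 of the 5 genes differed between them. Their choice by the rise in naive-like cells favours a smaller change in Treg-like cells, and Il4ra was not called without the mouse as a block. The comparison speaks at most against such a factor and not against other effects of the library. A response of naive-like cells to IL-4 stays a hypothesis that only part of the list goes with. Socs1 and Cish are members of the IL-2 and STAT5 list too, so their rise does not tell the 2 lists apart. Of that list 5 of 10 members rose and 2 fell in naive-like cells. Its median was 0.39 (camera with an estimated correlation, adjusted p = 0.618). Each condition was 1 droplet library, and a library effect cannot be told apart from infection.

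A second pattern is the fall of the type I interferon response genes over all CD4 T cells. If more blasts in infected mice were the whole cause, the fall would vanish without cycling cells and cluster 11, but the median was still -0.78, and without the SPF mouse whose loss weakened it most it was -0.98. A loss of cells of the interferon-response cluster alone would leave Treg-like cells unaffected, but 16 of 26 members fell in them by the test of each gene, though the list was not called there with an estimated correlation (adjusted p = 0.211) or by fry (0.0788). In activated cells 10 of 25 fell and in Tfh-like cells 4 of 18 (median -0.17, adjusted p = 0.529 with an estimated correlation), so the evidence against this explanation comes mainly from Treg-like cells, and naive-like cells decide nothing, because clustering on such genes set interferon-high cells apart from them. A lower interferon signal in infected mice and a difference between the libraries both stay open, as the design does not part them.

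The last pattern is cluster 11, which was found almost only in infected mice. Doublets of 2 T cells could hold 2 TRB chains in most cells, but 6.40% did (upper 95% limit 9.35%). A doublet of a T cell with another kind of cell could hold a single chain, so this value does not speak to it. Innate lymphoid cells, which the sort for TCRb would remove, would lack a TRB chain, but 95.2% of its cells had one (lower limit 92.5%). Invariant NKT cells would carry TRAV11 with TRAJ18, and 0 of 268 cells did, which allows up to 1.12%. Conventional T cell blasts formed during infection are a hypothesis that these values leave open and do not test. Doublets of a T cell with another kind of cell, other cells with a TRB chain and a state specific to the library stay open too.

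With 3 mice against 3 there are 10 splits of the mice, too few for a share under 0.05. The real split gave 6046 genes over all CD4 T cells (highest other 0), 3080 in naive-like cells (0), 663 in Treg-like cells (1), 1574 in Tfh-like cells (0), 606 in activated cells (0), 618 in the interaction (1) and 9 class shares (0), so 1 of the 10 splits reached each of these values. For TRAV and TRBV genes the real count and the highest other were both 0, reached by 10 of 10 splits. For gene lists the real split gave 13 over all CD4 T cells and another split 16, and 3 of the 10 splits reached 13. Within classes the real split gave 9 against 8 in naive-like, 15 against 13 in Treg-like, 17 against 10 in Tfh-like and 17 against 15 in activated cells.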

How the results depend on the processing

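The runs without cells with a second TRB chain, without cells of other types, without blasts, with the interferon-response cluster, without heat shock cells, with random cells in their place and with the draw of clones kept were chosen after the data were seen; the others had been planned. Of 33 counts and shares, 336 values under the alternatives were kept, 19 counts moved by over 1.5 times, 13 values reversed and 6 lost a call. Kept means a count within 1.5 times of the main one, or a tested value with the same direction and side of the threshold. The exact permutation tests of 10 genes and 4 clonal comparisons could not pass the threshold in any run, so only their direction could change. Of the values of 226 named genes, 3812 were kept, 117 lost a call and 13 reversed; of those of 71 called lists, 589 were kept and 125 lost a call, all 71 with an estimated correlation and 16 with fry. The Scrublet run is left out of these totals, because it removed no kept cell.

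Fewer genes were called over all CD4 T cells with equal composition (3279) and without blasts (3590), in naive-like cells without heat shock UMIs (810), with as many random cells (1043) and with DESeq2 (1984), in Treg-like cells likewise (391, 327 and 349), in Tfh-like cells with equal numbers of cells (799), without heat shock UMIs (979) and with random cells (923), and in activated cells with equal numbers of cells (385) and DESeq2 (313). Random draws of as many cells gave losses of like size, so the smaller number of cells goes with most of the loss; for the other settings the cause was not tested. Tfh-like cells at resolution 0.5 gave 1949 calls, 1134 of them shared. For Tfh-like cells, omitting the low-count filter moved the median of all genes by 0.177 and DESeq2 by -0.22.

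Leaving out 1 mouse gave 4455 to 6861 genes over all CD4 T cells, 2145 to 2843 in naive-like, 444 to 556 in Treg-like, 1082 to 1467 in Tfh-like and 440 to 514 in activated cells, 415 to 567 in the interaction, 4 to 8 class shares, 13 to 15 lists over all cells, 53 to 59 lists within classes and 0 to 1 TRAV genes. The log2 ratio of the activated share was 0.52 to 0.84. Differences in clonal expansion kept their direction, at 0.525 to 0.857 percentage points over all cells, 0.659 to 1.70 in Treg-like cells (0.659 without infected replicate 2), -21.8 to -8.92 in Tfh-like cells (-21.8 without SPF replicate 2, -8.92 without SPF replicate 3) and -10.8 to -7.14 in activated cells. In 4 of these runs the number of cells drawn changed too; with it kept, the values were 0.516 over all cells without infected replicate 2, 1.68 in Treg-like cells without infected replicate 1, and -18.3 in Tfh-like and -5.51 in activated cells without SPF replicate 2. Differences in shares of cells, in percentage points, ranged over 0 for Il5 (-0.0141 to 0.00807), Il21 (-0.0963 to 0.0454), Ifng (-0.0881 to 0.104), Il10 (-0.0908 to 0.0313) and Il2 (-0.0154 to 0.106); Il5 reversed without SPF replicate 2, Ifng without SPF replicate 3 (0.0742) and, with Il21 and Il10, without infected replicate 1, and Il2 without infected replicate 3. Without thinning the differences were 0.00954 for Il5, 0.719 for Il21, 0.0680 for Ifng and 0.245 for Il10, and at 1000 UMIs 0.00803 for Il5. With TMM over classes the log2 ratio was -0.0129 for naive-like, -0.00634 for Treg-like and 0.53 for activated cells. The cause of these was not tested.

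Lists and genes that reversed were interferon gamma (-0.27), Igtp (-0.25) and Ifi47 (-0.0207) and the uncalled Cd74 (-0.0485) in naive-like cells with the interferon-response cluster, Igkc (-0.22) and Cd8a (-0.0132) without cells of other types, Il21 over all cells without infected replicate 1 (range without 1 mouse -0.42 to 0.0221), S100a4 (-0.0345) and Cxcr3 (-0.35, and -0.51 at resolution 1.5) in Treg-like cells and Pdcd1 (0.17) in Tfh-like cells at resolution 0.5, Il10 in Treg-like cells without heat shock UMIs (0.0847), and Xbp1 in the interaction without infected replicate 1 or 3 (range -0.0803 to 0.20). For Igkc, Cd8a and the interferon genes the cells removed or added carry these genes; for the others the cause was not tested. The medians of 3 more called lists changed sign where their calls were lost: trafficking in Tfh-like cells (0.56 to -0.13) and TCR-induced in Treg-like cells (-0.0886 to 0.0487) without heat shock UMIs, and Th2 in Treg-like cells without infected replicate 2 (0.15 to -0.0191). The activated class at resolution 0.5 and without heat shock UMIs gave no value, as too few cells or no such class remained.

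Hashtag numbers do not pair the mice: the correlations of deviations within a number were -0.0586 to 0.0851. Every SPF mouse correlated best with the infected mouse of its own number in naive-like cells (3 of 3 numbers, correlations 0.0262 to 0.0770). This held for every SPF mouse in none of the other comparisons and is a hint from the data, not from the design. The best match of each infected mouse was not computed. With the hashtag number as a block, 5789, 3309, 665, 1294 and 638 genes were called in all, naive-like, Treg-like, Tfh-like and activated cells, with 7 class shares, 13 lists over all cells and 60 within classes. Without the mouse block in the interaction 308 genes were called. Depth limits what can be called: at a simulated 2-fold change 70.3% of genes were recovered in Tfh-like cells.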

Other observations

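The tests of shared clones and the choice of H2-DMb2 in this part were made after the results had been seen, and none of them was planned.

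Cytokine shares of the unnamed clusters are given as values, and differences between clusters were not tested. Cluster 11, from infected mice, combined the cytotoxic genes Gzmb and Gzma and the tissue-homing receptor Cxcr6 with type 2 cytokines: after thinning, Il4 was seen in 24.4% of its infected cells, Il13 in 2.5%, Mki67 in 22.2% and Il21 in 1.39%. Cluster 4, led by Myb, Eomes and Xcl1, had Il21 in 1.21% of SPF and 1.16% of infected cells. Cluster 6, led by the early growth response genes Egr2 and Egr3, had Il21 in 2.47% and 2.04%. In naive-like cells, thinned to the same depth, Il21 was seen in 0.0138% of infected cells.

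In naive-like cells, H2-DMb2, the partner subunit of H2-DMa, was at 0.203 CPM in SPF and 27.1 CPM in infected mice, a log2 change of 6.95 ± 0.37 (edgeR, adjusted p = 7.71e-09), higher in 3 of 3 infected mice than in every SPF mouse. H2-DMa was at 32.7, 34.7 and 33.4 CPM in SPF mice whose naive-like cells had a heat shock UMI in 18.4%, 30.2% and 57.1% of cases.

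Expanded clones were asked for their classes. Class names were shuffled within a mouse 10000 times. The hypothesis was that Treg-like cells in clones of at least 2 lie in other clones than Tfh-like, Th1-like and cluster 11 cells. In infected mice 0 of 75 clones held both, against a mean of 9.50 in shuffles (permutation p = 0.0004), and 0 also against Tfh-like (mean 4.23, permutation p = 0.00860) and Th1-like cells alone (3.38, permutation p = 0.0336). In SPF mice 0 of 58 held both, against 3.24 (permutation p = 0.0038), but only 4 Treg-like cells lay in such clones, and against Tfh-like or Th1-like cells alone the permutation p was 0.109 and 0.143. In infected mice only 16 Treg-like cells lay in such clones. The shuffle takes the class of a cell as independent of its clone. A tendency of cells of 1 clone to be of 1 class would also lower the count, so clonal origin is not tested. The other classes were not paired with Treg-like cells. Tfh-like cells were also paired with Th1-like cells (5 clones in infected mice, shuffled mean 7.06) and cycling cells (6, mean 5.91). The permutation p values were not adjusted for the number of pairs. A second hypothesis, that Tfh-like and cluster 11 cells share clones, was left undecided: 8 clones held both, against 5.25 in shuffles (permutation p = 0.229).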
